A study of Phaeodactylum tricornutum with 6 samples.

How the data were processed

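Total RNA from low-iron (5 nM) and iron-replete (10000 nM) cultures of Phaeodactylum tricornutum was compared on 2-colour arrays. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase on a column, amplified to amino-allyl aRNA and coupled to Cy3 or Cy5 before competitive hybridization. The short source name calls both channels iron-limited, whereas the growth protocol of the second channel and the sample descriptions call that channel iron-replete, and the latter were followed.

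The values used were the log ratios that the authors deposited for each probe and array, taken as log2. How they were made from the scans (background correction, normalization, centring, filtering of spots, log base and direction) is not given in the sources used here. Every value was a whole multiple of 0.0005, as a mean of 2 values with 3 decimals would be. The array medians as deposited were 0.02, 0.03, 0.05, 0.05, -0.12 and 0.03 for arrays 1 to 6. No scaling or centring was added in the main analysis, because an array built for selected genes need not have a median of 0. All 6 columns of the table were used.

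The 6 arrays formed 1 group and were numbered in accession order, which is also the order of the slide numbers in the labels. By a rule fixed before the data were examined, array 5, the dye swap, was to be turned if its correlation with the mean of the others was below -0.3 and used as deposited if it was above 0.3. It was 0.76, so the array was used as deposited. Each probe's mean ratio was tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over the 701 probes and a threshold of 0.05. Probes needed values on at least 4 arrays, which all had. The design, the alternatives and the rule for named probes were also fixed before the data were examined. The rule took the 12 highest and 12 lowest called probes of 1 sign on every array. Since no identifier could be matched to a gene, 2 per direction are printed and the rest are summarised. The identifiers were compared with the gene IDs, locus tags, symbols, synonyms and accessions of the 10398 genes of the reference annotation ASM15095v2, and none matched. The 14 gene lists fixed for iron uptake, photosynthesis, respiration, nitrogen metabolism and other pathways, and the set tests on them, could therefore not be run, and values of several probes per gene could not be combined.

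The fit was tested on simulated log ratios with the probe SDs of these arrays for the comparison of low and replete iron. In 50 simulations of 701 probes, with 34 probes changed at each of 3 sizes, the 6-array fit recovered 58.7% of probes changed by 0.25, 94.1% of those changed by 0.5 and 99.3% of those changed by 1. Of its calls 4.2% were false. The fit on means of 3 and 3 arrays recovered 30.6%, 90.5% and 98.9%, with 4.71% of its calls false. The simulated arrays were independent, which hybridizations of the same RNA are not. Changed probes drew their SD at random from all probes, whose median SD was 0.16, while the called probes had a median SD of 0.29. Array offsets, dye effects and exact zeros were not simulated. The recovered shares may therefore be too high for these data, and the shares of false calls too low.

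Alternatives fixed in advance were leaving out each array, a dye term, median-centring, scaling to 1 median absolute deviation, robust regression, an absolute log2 ratio of at least 1, and 2 ways to treat the unknown culture pairs over all 10 partitions of the arrays into 3 and 3 (means of each set, or a random block), which assume the 2 pairs of the sample descriptions. The alternatives chosen after seeing the data were reading exact zeros as missing, using arrays 1, 4 and 5 only, and centring together with leaving out array 5.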

Results

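RNA from the marine pennate diatom Phaeodactylum tricornutum, a unicellular alga widely used as a laboratory diatom, was compared between iron-limited and iron-replete cultures on a partial-genome array. The low-iron medium held 5 nM iron and the replete medium 10000 nM, and cells were harvested after 11 days at 18 °C. Each array carried both RNAs in different dyes, so that the log ratio of an array is itself the comparison. The table held 701 probes, each with a value on all 6 arrays. On 5 arrays the low-iron RNA was in Cy5, and on array 5 the dyes were swapped. By the sample descriptions, 2 cultures were grown per condition and each pair of cultures was hybridized 3 times. The labels do not settle which pair an array carried: the source name ends in Rep2 on every array, which read literally would put all 6 on 1 pair of cultures. The p-values below therefore measure mostly, or only, the spread between hybridizations. No signal intensity or background was used here, and the number of arrays limits the precision.

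The direction of the ratio is likely low over replete iron. Low-iron RNA is the first channel of every array, and the series is described as a response to iron limitation. Array 5 correlated with the mean of the other 5 arrays at r = 0.76 across probes, so its deposited ratio already ran the same way as theirs. If the shared pattern comes from the RNA, the ratio followed the channel or the condition, not the dye. The correlation alone cannot tell this from dye effects of single probes shared by all arrays. Nothing in the table states the direction outright. If the ratio were replete over low iron, every sign given here would turn, positive and negative counts would change places, and total counts and absolute sizes would stand. The log base is also not stated. The values are read as log2, in which case 1 unit is a 2-fold difference.

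The first question was how much of the array responded to iron. A minority of probes were called as differing between the 2 RNAs. Probes that were not called may also differ, by small amounts above all. Since the culture pair of each array is unknown, the calls cannot separate iron from differences between cultures. Of the 701 probes, 68 (9.7%) passed the threshold, 35 with a positive ratio (likely higher in low iron) and 33 with a negative ratio (likely lower). The positive probes had mean log2 ratios from 0.22 to 1.99, with a median of 0.45. The negative probes lay between -2.04 and -0.27, with a median of -0.54. Only 9 probes had an absolute mean of at least 1, and all 9 were among those called, 4 positive and 5 negative. At the other end, 611 probes (87.2%) had an absolute mean under 0.25. The test was limma's moderated test of the mean ratio against 0, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The unadjusted p was under 0.05 for 134 probes. The count was 18 (12 positive, 6 negative) when a dye term gave both dye orientations equal weight, 24 (14 and 10) without array 5, and 43 to 114 when arrays were first averaged within each of the 10 possible assignments to 2 culture pairs.

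**Figure D1:**
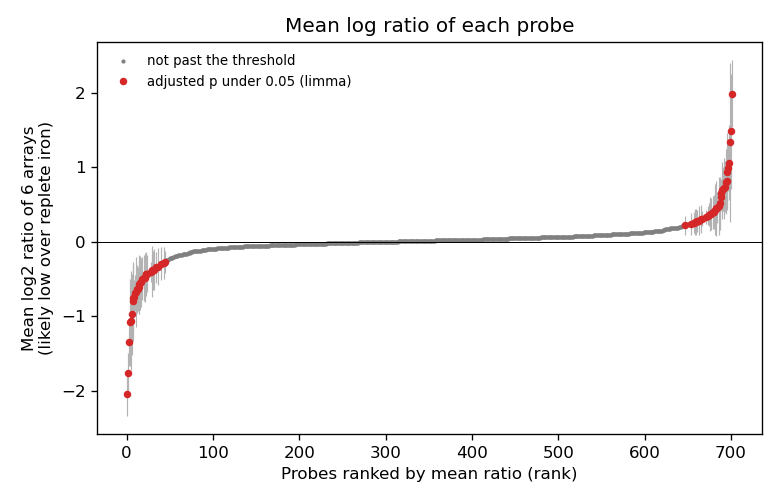
Mean log2 ratio of the 6 arrays (vertical axis, likely low over replete iron) for the 701 probes ranked from lowest to highest (horizontal axis). Red points are the 68 probes past the adjusted threshold of limma with bars of 1 SD over arrays, grey points the other 633, whose means lie between -0.49 and 0.48.

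The table does not pair its probe identifiers with genes, and none of the 701 identifiers matched the annotation used here, so the called probes are described by identifier and by name series. Among the called probes of 1 sign on every array, the largest positive ratio was that of probe Pha_54. Its mean log2 ratio was 1.99 ± 0.45 (SD, n = 6 arrays), with an adjusted p of 1.5e-05 in limma, and the single arrays ranged from 1.31 to 2.58. Probe C0002-2017 followed among them, at 1.06 ± 0.50 (SD, n = 6) with an adjusted limma p of 0.0026. Its lowest value, 0.22, was on array 3, and with the dye term its adjusted p was 0.064 in limma: the ratio stayed, at 1.07, while its moderated SE rose from 0.15 to 0.24. The lowest ratio was that of probe C0186-817, at -2.04 ± 0.30 (SD, n = 6), with an adjusted limma p of 1.3e-06. Array 6 gave its farthest value, -2.62, while the other 5 arrays lay between -2.08 and -1.83. Probe C0311-631 had a mean log2 ratio of -1.76 ± 0.27 (SD, n = 6), with an adjusted limma p of 1.3e-06 and values from -2.10 to -1.44. For the 4 probes named by the rule the distance from 0 was more than 2 SD of the arrays.

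**Figure D2:**
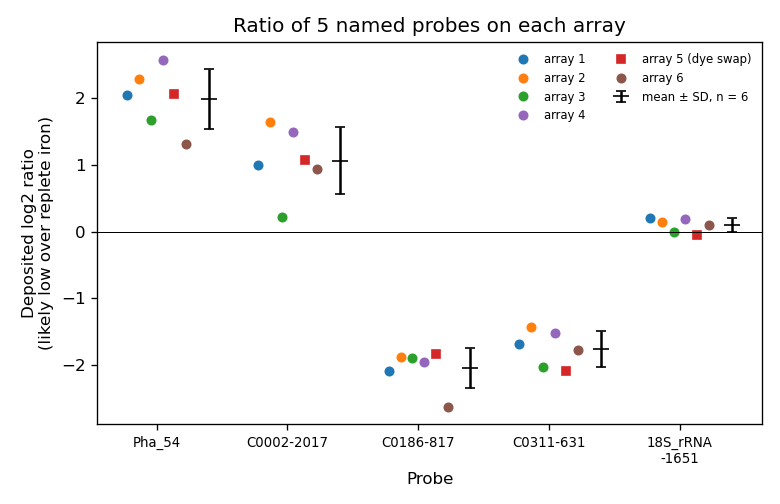
Deposited log2 ratio (vertical axis, likely low over replete iron) of 5 probes (horizontal axis) on each of the 6 arrays, with the dye-swapped array 5 as a square and the mean with 1 SD (n = 6) in black. Pha_54 lies between 1.31 and 2.58 and C0186-817 between -2.62 and -1.83, while the 18S_rRNA-1651 probe lies between -0.06 and 0.20.

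The 18S_rRNA-1651 probe, the only one whose identifier names its RNA, was picked for that name. The 18S rRNA is the RNA of the small ribosomal subunit. Its mean log2 ratio was 0.10 ± 0.10 (SD, n = 6), and it did not pass the test, with an adjusted limma p of 0.43. It was positive on arrays 1, 2, 4 and 6, listed at exactly 0 on array 3, and -0.06 on array 5.

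The direction of the called probes was shared by all arrays in most cases. Among the 68 called probes, 40 had 1 sign on all 6 arrays, 25 positive and 15 negative. Of the remaining 28, 8 had opposite signs on different arrays, and the other 20 had 1 sign apart from an exact 0. The test on the same arrays selects probes whose arrays agree, so the shared direction of the calls is no separate support. Of all probes, 65 (9.27%) had 1 sign on every array, where independent and equally likely signs without zeros would give 3.125%. That share is only a rough guide, since probes with an exact 0 were counted as not of 1 sign and array medians were not 0. The 12 highest of the 25 positive probes had means from 0.43 to 1.99, and the 12 lowest of the 15 negative ones had means from -2.04 to -0.37.

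The calls were spread unevenly over the series of probe names, whose meaning is not given in the sources used here. Identifiers starting with C made up 192 probes, of which 46 (24.0%) were called, 22 positive and 24 negative. That share was 8.85% without array 5 and 7.29% with the dye term, against 1.38% and 0.786% of the other probes. The Pha series had 12 of 220 probes called (5.45%), 8 of them positive. The PTMM series had 8 of 198 called (4.04%), 4 in each direction. The GS series had 2 of 56 called and the PTAM series none of 26. The tests on name series were chosen after the calls had been seen, and they take probes as independent, which probes need not be, so their p-values may be too small. By Fisher's exact test against all other probes, adjusted over the 5 series with at least 20 probes, the C series held more calls (adjusted p = 1.4e-12), and the Pha and PTMM series fewer (adjusted p = 0.015 and 0.0025), against a rest that includes the C series. Outside the C series 22 of 509 probes (4.32%) were called, and none of the other 4 series passed Fisher's exact test against the remaining probes there. The lowest unadjusted p was 0.28, for the Pha series at 5.45% against 3.46%. In the PTAM series, 5 probes had an unadjusted p under 0.05 in limma. The main fit called none of its probes, while 1 or 2 were called in some alternatives, among them 1 with exact zeros as missing and 1 in all 10 assignments of arrays to culture pairs.

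The second question was how far the hybridizations agreed. Across all probes, the 15 pairs of arrays had Pearson correlations from 0.37 to 0.75, with a median of 0.60. The lowest pair was arrays 1 and 3 and the highest arrays 4 and 5. No pair of arrays held the same values. The median Spearman correlation was lower, at 0.33. Over the 68 called probes alone, which were selected for agreeing across arrays, the median Pearson correlation was 0.88. Probes are not independent replicates, so no p-value is attached to these correlations. The median SD of a probe over the 6 arrays was 0.16, and that of the called probes 0.29.

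Arrays 2, 3 and 6 listed many probes at exactly 0, and these zeros entered the means above. Array 3 had 138 such probes (19.7%), array 2 had 75 and array 6 had 71, against 5 to 8 on arrays 1, 4 and 5. Among the 68 called probes were some listed at 0 on an array while the others lay far from 0. Probe Pha_63, chosen after its values were seen, had a mean of 1.34 over all 6 arrays and 2.00 over the 4 arrays where it was not at 0, close to the 1.99 of Pha_54. When exact zeros were read as missing, 76 of 698 probes passed the threshold in limma, 38 in each direction, and all 68 were among them.

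**Figure D3:**
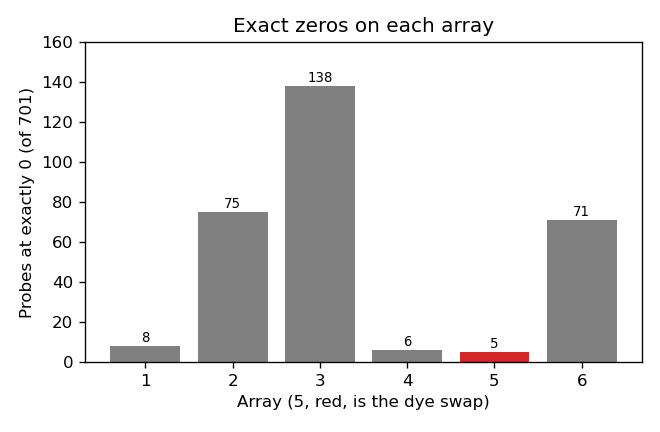
Number of probes at exactly 0, of 701, on each of the 6 arrays, with the dye-swapped array 5 in red. Arrays 2, 3 and 6 had 75, 138 and 71 such probes and the other arrays 5 to 8.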

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

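Apart from the fit without array 5, which was fixed in advance, the tests in this part were chosen after the array medians and zeros had been seen. For the overlap of zeros between arrays and the tests on array 5, the outcomes were predicted before the tests were run; the unadjusted and centred counts for array 5 were added afterwards. Dixon's test was applied to 4 measures of the arrays and 5 probes, each over 6 arrays, and 2 of the 9 stood apart, where chance gives about 1 in 20.

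The dye-swapped array 5 had a median log2 ratio of -0.122, while the medians of the other 5 arrays lay between 0.0165 and 0.0545. Leaving it out lowered the calls from 68 to 24, although the probes with an unadjusted p under 0.05 rose from 134 to 178, 123 of them positive. Dye effects that differ from probe to probe stay open. Array 5 differed from the other 5 arrays at 0 probes after adjustment in limma, against up to 5 for another array, but with 1 swapped array this says little: its unadjusted count, 111, was the highest of the 6 arrays, and after centring it was 42, below the 81 of array 1. An offset of each array's median may account for part of the loss: after centring, 56.1% of the calls remained without array 5, which lies between the predictions for this cause and against it, so a dye-wide shift and an offset of that array cannot be told apart with 1 swapped array.

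Probe C0186-817 read -2.6235 on array 6, below the range of the other 5 arrays, from -2.084 to -1.8305.

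Exact zeros were frequent on arrays 2, 3 and 6. They were not measured ratios that round to 0: the values within 0.01 of 0 led to an expected 2.3 zeros on these arrays, and 284 were found. On array 3 they may be spots without a usable ratio, written as 0 whatever the probe's ratio. There 17.4% of the probes with an absolute mean of at least 0.3 over the other arrays' non-zero values were at 0 (15 of 86), against 20% of the rest (two-sided Fisher's exact p = 0.66). That reading is argued against for array 2, at 1.22% against 12% (Fisher's exact p = 0.003 after adjustment over the 3 arrays), and stays open for array 6, at 3.75% against 11% (Fisher's exact p = 0.048 before adjustment and 0.071 after). For array 2 the shares speak only against zeros that fall whatever the probe's ratio. Unusable spots that are more frequent among probes near 0 could give the same shares. These tests take spots as independent, which they need not be. The adjustment, and the use of non-zero values only for the split, were both chosen after these shares had been seen, and the array 6 label turns on the adjustment. The few zeros of arrays 1 and 4 went the other way, at 6.33% against 0.482% and 4.05% against 0.478%. The same probes tended to be at 0: 59 were so on at least 2 of the 3 arrays, against 33.4 on average when zeros were shuffled (permutation p = 0.0001, the smallest that 10000 shuffles can give), so a property of the probes, such as a dim signal, stays open, and no biological explanation was tested.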

How the results depend on the processing

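The number of called probes depended on the treatment of the dye swap and of the culture pairs more than on scaling. It was 68 (35 positive, 33 negative) as reported. Leaving out each array in turn gave 24 to 73 calls, 14 to 38 positive and 10 to 40 negative. The lowest values of each came without array 5, and without array 4 the positive calls were 23. The dye term left 18 calls, 12 positive and 6 negative. By construction this fit gives array 5 as much weight as the other 5 arrays together. Requiring an absolute ratio of at least 1 left 9 (4 and 5). Means of 2 sets of 3 arrays gave 43 to 114 calls over the 10 assignments, 25 to 59 positive and 18 to 55 negative, and 41 probes (24 and 17) were called in all 10, of which 38 were among the 68. A random block gave 72 to 128 calls (up to 68 and 60) and kept all 68 in every assignment. Its estimated within-set correlation was negative in each, which narrows the error of the mean. The random block could therefore hardly lose calls, and the kept 68 do not show that shared cultures leave the calls unchanged. Centring together with leaving out array 5 gave 33 (14 and 19). Centring alone, scaling, robust regression, exact zeros as missing and arrays 1, 4 and 5 only gave 57, 67, 62, 76 and 68. The median correlation between arrays was 0.60 by Pearson, 0.3255 by Spearman and 0.8774 over called probes. The 5 named probes (4 by the rule and 18S_rRNA-1651) kept their direction in all 70 values computed for them, and their side of the threshold in 69. These values leave out the random block and the ratio threshold. The 4 probes of the rule were picked for 1 sign on every array, so their direction could hardly turn. The values for means of 2 sets repeat the main ratio. The kept direction is therefore no separate support. The exception was C0002-2017 under the dye term (adjusted p = 0.064 by limma, and at most 0.038 in its other values). Its ratio was 1.07 there against 1.06 in the main fit, and its moderated SE 0.24 against 0.15, so the call ended through a wider error and not a smaller ratio. The filter on incomplete probes removed none, and the gene list and probe-per-gene alternatives were not run because no probe could be matched to a gene. Signal over background, which would show which ratios rest on dim spots, was not used here. The causes of these changes were not tested beyond array 5.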

Other observations

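The tests on name series in this part were chosen after the calls had been seen; the count of sign patterns was planned before. Fisher's test takes probes as independent, which they need not be, so its p-values may be too small. Probes whose identifiers start with C were called more often than the others, also in each of 13 alternative fits (leaving out each array, the dye term, centring, scaling, robust regression, zeros as missing, arrays 1, 4 and 5 only, and centring without array 5). These fits reused the same arrays, and the series was picked after the calls were seen, so they are no separate support. The share of C probes called in the main fit was 24.0%, against 4.32% of the other 509 probes. With the dye term it was 7.29% against 0.786% (Fisher's exact p = 9.48e-06), and without array 5 it was 8.85% against 1.38% (p = 8.03e-06). The spread was not lower: the median SD over arrays was 0.19 for C probes and 0.15 for the rest. The ratios themselves were larger: 26.6% of C probes and 4.91% of the others had an absolute mean of at least 0.3. How the probes were chosen for the array is not given in the sources used here.

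The signs of the arrays can be turned in 32 distinct patterns. Only 1 of them, the real one, gave as many as 68 calls, and the highest count of the other patterns was 8. A share of 1 in 32 is the smallest that this count can give, so chance in the signs of independent arrays is not excluded. The dye-swapped array would also have been turned by the rule had it run against the others, so its sign was not free. The count says nothing about cultures, since hybridizations of the same RNA are not independent.

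After subtracting each probe's mean over the 6 arrays, 13 of the 15 pairs of arrays had negative correlations, where independent arrays would give -0.2 on average. The exceptions were arrays 4 and 5, at 0.15, and arrays 3 and 6, at 0.07. These values do not show which arrays shared a culture pair.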
